A study of Eohaustorius estuarius with 16 samples.

How the data were processed

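Total RNA from whole bodies of the amphipod Eohaustorius estuarius was labelled with Cy3 and hybridised to a custom Agilent array, 1 sample to an array, in 1 colour. There were 8 control samples (sediment spiked with solvent) and 8 exposed samples (sediment spiked with cyfluthrin, nominal 1.6 micrograms per kilogram), both kept for 10 days. Groups were taken from the labels' treatment field and replicate numbers from the sample titles. Per the labels' protocols, RNA was purified on RNeasy columns by every laboratory of the study except 1 that used another reagent, and which laboratory that was is not given in the sources used here.

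The deposited files hold 1 array each, as Agilent Feature Extraction output. Per the file headers, the version was 10.7.1.1, whereas the submitters' processing notes give 9.1. Per the file headers, the processed spot intensity is the Cy3 brightness on a linear scale after background subtraction and spatial detrending, with no normalization between arrays, so that array brightness remained in it. The files also give the raw median intensity of each spot and of its local background, and flags per spot for signal well above background, positive and significant signal, saturation and outliers. The authors also deposited a table of log2 values of the same arrays, of which the normalization is not stated in the sources used here. Of its probes, 100% had a median of 0 over the 16 arrays (within 1e-06), and every array had a mean of 0.0253. Its columns correlated with quantile-normalized scanner values centred in the same way, with a lowest correlation of 0.990 across probes. Its array medians were -0.0952, 0.14, 0.020, -0.041, 0.0027, 0.017, 0.0094 and 0.0059 for controls 1 to 8, and -0.017, -0.018, -0.0042, 0.011, -0.0015, -0.0035, 0.032 and -0.051 for cyfluthrin 1 to 8. The scale (log2), the centring by probe and the direction were thus settled from the values, and the exact normalization stays unknown.

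Of the 15744 spots of an array, 536 were control spots and were left out. The remaining 15208 spots carried 8507 probes, each for a different contig of a transcript assembly, with 1 spot for 2249 probes, 2 spots for 6208 and 10 or 11 spots for 50. The values tested were log2 of the processed intensity, averaged over the spots of a probe, minus the 75th percentile of these values on the same array. A probe was tested where it was well above background on at least 4 of the 8 arrays of at least 1 group, on at least 50% of its spots. This kept 7245 probes and left out 1262.

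Cyfluthrin and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, all 16 arrays, no block), with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. A probe is said to have risen or fallen where it passed that threshold. Intervals are 95% confidence intervals of limma's coefficient. Single quantities per array were compared with exact permutation tests over all 12870 splits of 16 arrays into 8 and 8, two-sided for differences between means and one-sided for shares of variance. The spread of a group was measured per array, as the median over tested probes of the absolute deviation from the group mean, and per probe, as the variance within the group. Tables were handled with the R package data.table, version 1.17.8, and figures drawn with matplotlib 3.10.9 in Python 3.11.15.

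The files and labels used here pair no probe with a gene name. The 21 gene lists that had been fixed for a test of groups of genes (detoxification, ion channels, muscle, cuticle, germ line and others) could therefore not be tested, and no housekeeping gene could be named. The rule for this case, also fixed before the data were examined, was to name at most 2 probes that rose and 2 that fell, those with the smallest p.

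The slide and the scan were read from the file headers. There were 2 slides, each scanned apart from the other, so slide and scan cannot be separated. Slide 1 held replicates 1 to 4 of both groups, with controls in row 2 and exposed samples in row 1. Slide 2 held replicates 5 to 8 of both groups, with controls in row 1 and exposed samples in row 2. Each slide thus held 4 control and 4 exposed arrays, and the comparison was also made with the slide as a block and on each slide alone. In this layout the row of a slide and a difference in effect between slides are the same term.

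For arrays, depth takes the form of signal over background. Between 76.0% and 86.2% of the probes of an array were well above background, and the 75th percentile of the intensity lay between 421 and 1011. The number of arrays limits the precision. The SD between the 2 spots of a probe on an array had a median of 0.094 on the log2 scale over 5310 tested probes with 2 spots, against 0.41 between arrays of a group. The test was run on simulated arrays with the means and SDs of the 7245 probes, in which 200 had been changed. It recovered 29.9% of the probes changed 1.5-fold, 65.7% of those changed 2-fold and 89.4% of those changed 4-fold, and 10 of its 133 calls were false. The simulated noise was normal and independent between probes, with the same SD in both groups and no effect of slide. The measured arrays differ in this, so these rates may not hold for them.

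Alternatives tried were normexp background correction, quantile normalization, the median in place of the 75th percentile, a 75th percentile over probes above background on all arrays, the authors' log2 table, 2 other filters on dim probes, leaving out outlier spots, blocks for slide, slide row and replicate number, array weights, another variance model, other thresholds and leaving out arrays. The planned normexp correction of mean intensities was run on median intensities with an offset of 50, since the columns used here hold medians.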

Results

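Eohaustorius estuarius, a burrowing estuarine amphipod used in sediment toxicity tests, was kept for 10 days in sediment spiked with cyfluthrin at a nominal 1.6 micrograms per kilogram or in sediment spiked with solvent. Cyfluthrin is a pyrethroid insecticide, a class that acts on the voltage-gated sodium channels of nerve cells. Whole-body RNA of 8 control and 8 exposed samples was measured on 16 arrays. The series is part of a comparison of microarray results between laboratories and holds the whole-body samples of the laboratory labelled B. The other laboratories' arrays were not analysed here. The labels do not say how many animals made up a sample or whether samples came from separate aquaria. The p-values thus set the difference between groups against the spread between these samples, part of which may be technical. No spot had exactly the same processed intensity, compared without rounding, on both arrays of any pair (0% of spots), and the correlation of a pair of arrays lay between 0.802 and 0.980 across tested probes.

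The main comparison asked which transcripts differed in abundance between exposed and control amphipods. Of 7245 tested probes, 360 (4.97%) changed, of which 103 rose and 257 fell in the exposed samples (limma, adjusted p under 0.05). Most changes were modest. The median change was 1.62-fold among both the rises and the falls, and 39 rises and 43 falls reached 2-fold. Among changed probes that were well above background on all 16 arrays, 82 rose, by up to 8.22-fold, and 231 fell, by up to 8.42-fold. These transcripts are known here by contig only, so that no function can be given for them.

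**Figure D1:**
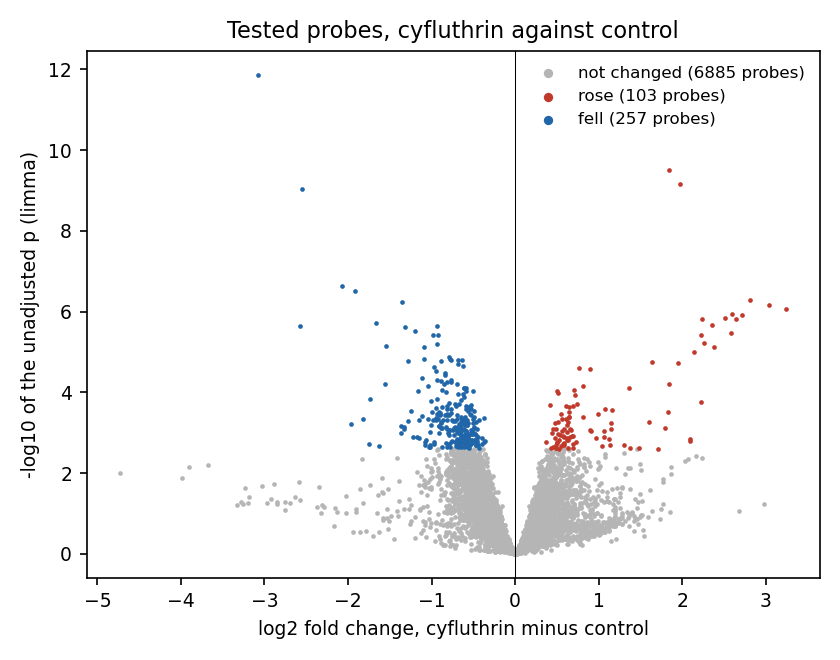
Each point is 1 of the 7245 tested probes, with the log2 fold change (cyfluthrin minus control, 8 arrays each) on the x axis and -log10 of the unadjusted limma p on the y axis. The 103 probes that rose are red, the 257 that fell are blue, and the rest are grey.

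Changed transcripts were found at every level of brightness. With the tested probes split by mean signal into 3 classes of 2415, the dimmest class held 28 rises and 85 falls, the middle class 31 rises and 99 falls, and the brightest class 44 rises and 73 falls. In 69 of the changed probes, all 8 exposed arrays lay on the same side of all 8 controls, 22 of them above and 47 below. Over all tested probes such a separation was seen in 71, where 1.13 would arise by chance (0.0155% of probes for 8 against 8).

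The excess of falls over rises depended on how the arrays were scaled, and it was not seen on both slides. With the 75th percentile, slide 1 alone gave 23 rises and 3 falls, and slide 2 alone 13 rises and 62 falls. Quantile normalization gave 155 rises and 211 falls, the authors' log2 values 158 rises and 214 falls, and scaling to the median of each array 168 rises and 138 falls, beside the 103 and 257 of the 75th percentile. When 1 array at a time was left out, the count of changed probes moved by over 1.5 times for 7 of the 16 arrays: it was 176 without control 2, 140 without control 6, 204 without control 7, 225 without control 8, 672 without cyfluthrin 2, 183 without cyfluthrin 5 and 226 without cyfluthrin 8.

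The transcript with the smallest p was that of contig 2561 (probe CUST_4125_PI425439380), which fell 8.42-fold. Its normalised log2 signal was 2.65 ± 0.39 (SD, n = 8) in controls and -0.42 ± 0.23 (SD, n = 8) in exposed samples, a log2 change of -3.07 ± 0.16 (SE; 95% interval -3.42 to -2.73; limma adjusted p = 9.84e-09). The transcript of contig 2087 (CUST_4119_PI425439380) fell 5.87-fold, from 1.35 ± 0.44 (SD, n = 8) to -1.21 ± 0.40 (SD, n = 8), with a log2 change of -2.55 ± 0.21 (SE; 95% interval -2.99 to -2.11; limma adjusted p = 1.70e-06). For both, the highest exposed array lay below the lowest control array. On slides 1 and 2 taken apart, the log2 change was -2.97 and -3.18 for contig 2561, and -2.33 and -2.78 for contig 2087.

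The rise with the smallest p was that of contig 2633 (CUST_190_PI425439775), at 3.58-fold. Its signal went from 0.43 ± 0.24 (SD, n = 8) in controls to 2.27 ± 0.28 (SD, n = 8) in exposed samples, a log2 change of 1.84 ± 0.14 (SE; 95% interval 1.54 to 2.13; limma adjusted p = 1.12e-06). The transcript of contig 1240 (CUST_2670_PI425439380) rose 3.92-fold, from 0.99 ± 0.26 (SD, n = 8) to 2.96 ± 0.34 (SD, n = 8), with a log2 change of 1.97 ± 0.16 (SE; 95% interval 1.64 to 2.30; limma adjusted p = 1.63e-06). Again no exposed array overlapped the controls. The log2 change on slides 1 and 2 was 1.75 and 1.93 for contig 2633, and 2.24 and 1.70 for contig 1240. All 4 probes were well above background on all 16 arrays.

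**Figure D2:**
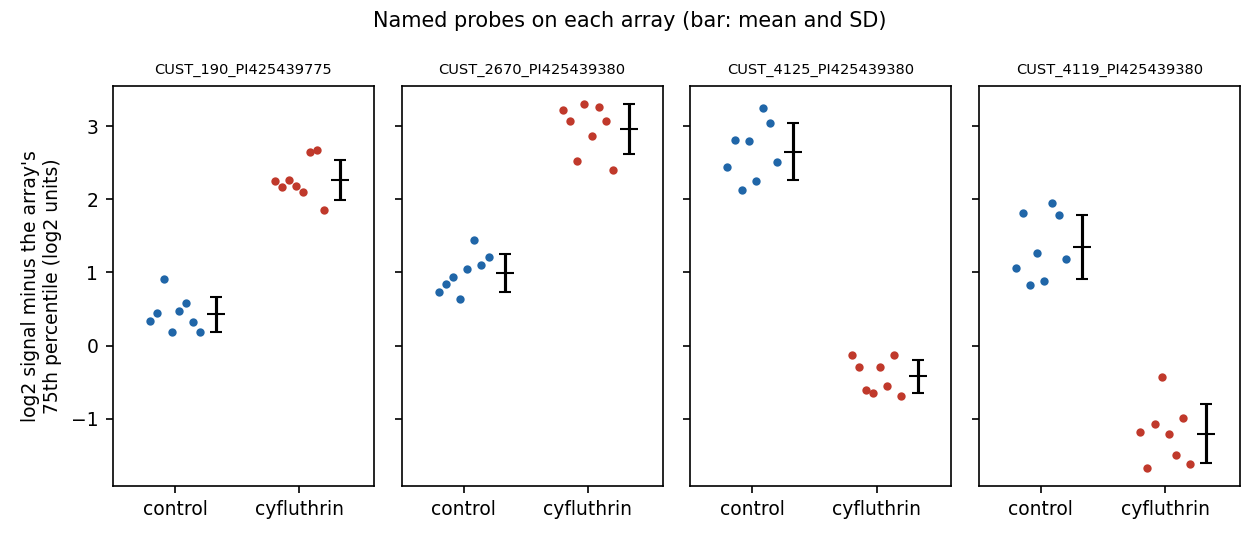
Each panel shows 1 named probe, with a point for each array (8 control in blue, 8 cyfluthrin in red) and a bar for the mean and SD of each group, and the y axis gives the log2 signal minus the 75th percentile of the array. In every panel the 8 exposed arrays lie apart from the 8 controls, above them for the first pair of probes and below them for the second pair.

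The slides carried separate arrays of both groups, so that the same transcripts could be compared on 2 sets of arrays. Within a slide, all exposed arrays lay in the same row and all controls in the other. On a slide taken alone, exposure and row therefore cannot be told apart. All 360 changed probes had the same direction on both slides, although both slides contributed to their selection. Of the 26 probes that passed the threshold on slide 1 alone (23 rose, 3 fell), all 26 had the same direction on slide 2, and 22 also had an unadjusted limma p under 0.05 there. Of the 75 that passed on slide 2 alone (13 rose, 62 fell), 68 had the same direction on slide 1, and 27 also had an unadjusted p under 0.05 there. The same direction was seen for 59 of the 62 falls but only 9 of the 13 rises. On both slides, 5 probes passed the threshold. An unadjusted limma p under 0.05 was seen for 613 probes on slide 1 and 1769 on slide 2. Over all tested probes, 68.1% had the same direction on both slides, and the log2 changes of the slides correlated at 0.33 across probes, which are not independent replicates. With the slide as a block, 461 probes changed, 142 upwards and 319 downwards. No probe passed the threshold for a difference in response between slides by limma (0 with an adjusted p under 0.05; 416 with an unadjusted p under 0.05, where 362 would arise by chance). With so few arrays of each group on a slide, this test cannot show that the responses were equal. In this layout it is also the test of slide row.

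**Figure D3:**
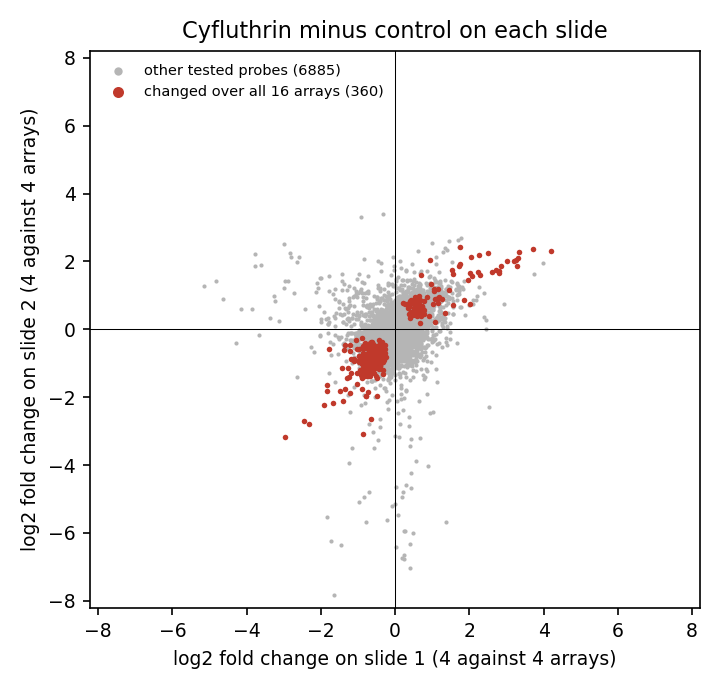
Each point is a tested probe, with its log2 change (cyfluthrin minus control) on slide 1 on the x axis and on slide 2 on the y axis, from 4 against 4 arrays on each. The 360 probes changed over all 16 arrays are red and all lie in the quadrants of equal direction.

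Exposure accounted for a limited part of the variation between samples. The difference between groups held 12.9% of the total variance of the tested probes, where 6.67% would arise without any difference (exact permutation p = 0.0319). The difference between slides held 12.7% (exact permutation p = 0.0359), and 240 probes differed between slides with group and slide row in the model (limma, adjusted p under 0.05). Slide row held 6.69% (exact permutation p = 0.410).

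Exposed arrays also varied more among themselves than control arrays did. The median variance of a probe was 0.199 among exposed arrays and 0.109 among controls, a ratio of 1.82, and 73% of the tested probes had the larger variance among exposed arrays. Exposed arrays lay 0.30 ± 0.053 (SD, n = 8) from their group mean on the log2 scale and controls 0.22 ± 0.039 (SD, n = 8), a difference that passed the threshold of 0.05 (two-sided exact permutation p = 0.00513). The ratio itself was not tested, and each exact permutation p beside a ratio below is that of the difference in mean distance. In tests by slide that were chosen after seeing the data, the ratio was 1.91 with deviations taken within slides (exact permutation p = 0.00122). On slide 2 alone it was 2.39 (exact permutation p = 0.0286, the smallest that 4 against 4 arrays can give). On slide 1 alone it was 1.69 (exact permutation p = 0.0857), where the difference in distance did not pass the threshold. Exposed arrays also differed more in brightness, with an SD of the log2 75th percentile of 0.38 against 0.21 in controls. With quantile normalization the ratio was 1.66 (exact permutation p = 0.0146). Whether the larger spread was technical was not tested.

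**Figure D4:**
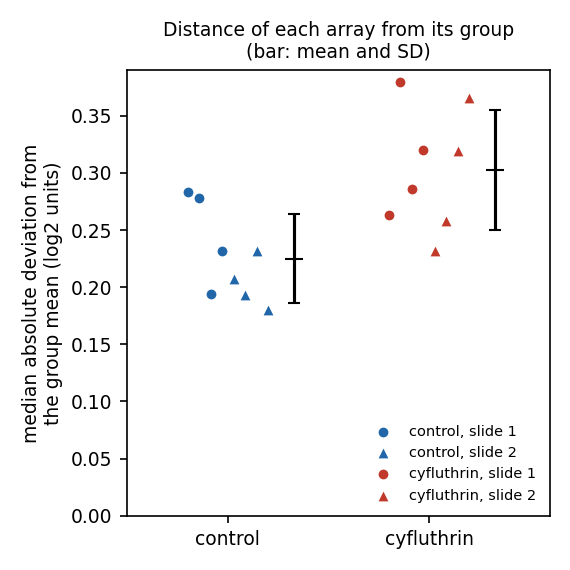
Each point is an array (circles, slide 1; triangles, slide 2), and the y axis gives the median absolute deviation of its tested probes from the mean of its group, in log2 units. Bars give the mean and SD of each group, 0.22 ± 0.039 for 8 controls and 0.30 ± 0.053 for 8 exposed arrays.

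The share of probes well above background was 81.2% ± 2.90 (SD, n = 8) in controls and 83.6% ± 2.43 (SD, n = 8) in exposed samples. The difference of 2.47 percentage points was not larger than the spread between arrays (two-sided exact permutation p = 0.0883). It was 2.05 points on slide 1 (exact permutation p = 0.143), 2.89 points on slide 2 (exact permutation p = 0.257) and had an exact permutation p of 0.0804 when arrays were exchanged only within slides. A test of this share with same-numbered arrays as pairs was not run. The difference passed the threshold without control 3 (3.06 points, exact permutation p = 0.0354) and without cyfluthrin 7 (3.24 points, exact permutation p = 0.0120). The 75th percentile of log2 intensity was 9.14 ± 0.21 (SD, n = 8) in controls and 9.45 ± 0.38 (SD, n = 8) in exposed samples (two-sided exact permutation p = 0.0648).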

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

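In groups of 8 arrays, an array was picked out where its gap to the nearest other array exceeded Dixon's 95% critical value for the ratio of that gap to the group's range. Of 34 groups of values looked at, 6 held such an array, where chance alone would give 1.7 (1 in 20). The probe sets named below were formed after seeing the data, from 880 tested probes that lay over 2 log2 units from their own median on at least 1 array, so an outlying array in them is partly built in. The tests of position on the slide and of array brightness were chosen after the result was seen. So was the test of set A on single moved spots, once the test of single spots set beforehand had decided nothing. Chosen before were the tests of both spots in sets A, B and C and of absent transcripts in set A. The comparisons of the sets between groups and on each slide were made after the sets were formed, with no prediction written beforehand.

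Cyfluthrin 7 had the lowest share of probes well above background among exposed arrays, 78.2%, against 82.7% for the next. Control 1 stood apart in set E (35 probes), at 3.76 log2 units above the probes' medians against 0.62 for the next control and 0.96 for the highest exposed array, cyfluthrin 2, and in set G (27 probes), at 4.75 against 1.29, where cyfluthrin 3 (3.45, 10.9-fold) and cyfluthrin 6 (2.12, 4.35-fold) were high as well. Set B held 242 probes, none of them among the changed ones, that were low together in control 2 (-4.17 log2 units from their medians, 18.0-fold) and cyfluthrin 2 (-3.21, 9.28-fold), both picked out in their groups, against -0.70 and -0.39 for the next arrays. These 2 arrays share replicate number 2, slide 1 and slide column 2. Of the pairs with the same number, theirs had the highest correlation of deviations from the group means (0.478). That correlation was taken across probes that include set B, so it partly restates the same pattern. Both spots had moved in a share of 0.995 of the set's probes with 2 spots. These probes, too, had been picked for moving together on the average of their spots, so this share does not decide on faults of single spots. In its 75th percentile, 1 of the 2 arrays lay outside the range of the others, and a shared column was not tested.

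Set A held 145 probes that were high together in control 1 (4.20 log2 units above their medians, 18.4-fold), control 4 (2.70, 6.50-fold) and cyfluthrin 2 (4.20, 18.4-fold, which picked it out among exposed arrays), with cyfluthrin 8 next at 1.53 and none of the 145 among the changed probes. The test of single spots set beforehand left such faults open, since both spots had moved in a share of 0.860 of the probes with 2 spots. That share lies between the bounds of 0.5 and 0.9 (0.714 on control 4). In the test chosen after that, a share of 0.0103 of the probes with at least 1 moved spot had 1 spot moved without the other. The probes had been picked for moving together on the average of their spots. That made faults of single spots unlikely beforehand, so neither test decides on them. Array brightness alone is argued against by the log2 75th percentiles, of which 0 of the 3 lay outside the range of the other arrays. Cyfluthrin 5, the brightest at 9.98, stood at 0.43 in set A. A lesser part played by brightness stays open, since the rule counted against it once 1 array lay inside that range. Position on the slide stays open, since the other arrays of the same slide rows averaged -0.15 but could count as such only if under 2.5 log2 units. Transcripts absent from the other samples stay open too, since the share of 0.883 of the set above background in the median other array was raised by the filter on dim probes. Dim probes that were not tested were high most often in control 1 (66), cyfluthrin 2 (63) and control 4 (23). They were nearly as often high in cyfluthrin 1 (22), where set A was not raised (-0.13). The difference between groups did not pass (exact permutation p = 0.888), and differences in the state or the mix of animals between samples stay open as a candidate explanation, as no label describes sex, brood or moult and no such explanation was tested.

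Set C held 72 probes that were low together in cyfluthrin 5 (-4.63 log2 units), cyfluthrin 7 (-4.32) and cyfluthrin 8 (-4.51), up to 24.8-fold below their medians, while the remaining 13 arrays lay between -1.24 and 1.37. Both spots had moved in a share of 0.927 of the probes with 2 spots, above the 0.9 set against faults of single spots. The probes had been picked for moving together on the average of their spots. That made such faults unlikely beforehand, so the test does not decide on them. Only 1 of the 3 arrays lay outside the range of the others in its 75th percentile, which argues against array brightness alone. The log2 75th percentiles were 9.98, 9.34 and 9.68 for cyfluthrin 5, 7 and 8, against 8.72 to 9.95 for the others. Cyfluthrin 2, at 9.95, stood at 1.37 in set C. A lesser part played by brightness stays open, since the rule counted against it once 1 array lay inside that range. Position on the slide stays open, since cyfluthrin 6, the remaining array of that slide row, stood at 1.22 but is a single array that counts as remaining because it was not low. Exposure is the biological explanation that the design offers: the exposed arrays averaged -1.58 and the controls 0.27, a difference that did not pass (exact permutation p = 0.0819, adjusted p = 0.369 over 9 sets), with -0.10 on slide 1 (exact permutation p = 0.829) and -3.59 on slide 2 (exact permutation p = 0.114). An effect of exposure in some samples only and a difference between animals that exposure did not bring about both stay open.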

How the results depend on the processing

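Normexp on median intensities, slide and slide row as blocks, the slide block and each slide alone for the spread and the share of probes above background, and leaving out together the 4 arrays that stood apart (controls 1 and 2, cyfluthrin 2 and 8) were chosen after seeing the data. The 4 named probes kept their direction and stayed past the threshold under all 32 alternatives run for each, with limma adjusted p from 2.35e-09 to 0.0222. Of the 360 changed probes, 7 changed direction under normexp and 0 under the other 31 alternatives that refitted the model, of which the filter for probes above background on all arrays held 313 of the 360.

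The count of changed probes was within 1.5 times of 360 under 21 of 34 alternatives. It was 26 on replicates 1-4 alone and 75 on replicates 5-8 alone, where fewer arrays were tested, 574 with array weights, 189 without the 4 arrays that stood apart, 772 at an adjusted p under 0.10, and 694 at an unadjusted p under 0.05 with a fold of at least 1.5. Leaving out 1 array at a time gave 140 to 672: 176 without control 2, 140 without control 6, 204 without control 7, 225 without control 8, 672 without cyfluthrin 2, 183 without cyfluthrin 5 and 226 without cyfluthrin 8. The cause was not tested. Rises made up 28.6% of the calls, 42.3% with quantile normalization, 42.5% in the authors' table, 54.9% with scaling to the median, and 42.9% without the 4 arrays that stood apart. They made up 88.5% of the calls on replicates 1-4 alone and 17.3% on replicates 5-8 alone. Normexp gave 367 probes (81 rose, 286 fell), of which 291 were among the 360.

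The replicate block gave 411 probes (166 rose, 245 fell), of which 274 were among the 360. Same-numbered arrays share a slide and a slide column, but the labels do not say that a number marks a shared batch, and not every pair deviated together: the correlation of same-numbered arrays lay between -0.22 and 0.48 across probes, 4 of 8 exceeded 0.1, and 3 of 8 controls correlated best with the exposed array of their own number. The numbers were therefore not taken to pair the samples in the main test, but a pairing is not excluded. Differences within same-numbered pairs had an SD of 0.34 in set D and 0.73 in set B. The SDs within controls and within exposed arrays were 0.76 and 0.73 for set D, and 1.47 and 1.49 for set B. In no other set did the SD of pair differences lie below those of both groups. Set B is the only 1 of the 9 probe sets whose call changed with such pairs (given below).

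The ratio of variances kept its direction under 28 alternatives, from 1.61 to 2.39, and leaving out 1 array gave 1.61 to 2.06. The difference in mean distance from the group mean lost its call only on replicates 1-4 alone (exact permutation p = 0.0857, beside a ratio of 1.69). The difference in the share of probes above background lay between 1.54 and 3.24 points over 20 alternatives; leaving out 1 array gave 1.74 (without control 7) to 3.24 (without cyfluthrin 7), and it passed the threshold without control 3 (3.06) and without cyfluthrin 7. Not run were the alternatives for gene lists, which need gene names, a scan date block, which equals the slide block, and normexp on mean intensities. Without the filter on signal over background, with 1262 more probes in the adjustment, 278 probes changed, of which 272 were among the 360.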

Other observations

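The grouping of probes into sets that vary together, the test of random placement of neighbouring probe numbers, the test of the correlation of neighbours (a similar correlation had been looked at before its bounds were set) the test of the sets with same-numbered arrays as pairs and the look at untested probes were chosen after seeing the data; for the split of the arrays into other groups and the distance on the glass, what each explanation predicts was written before the result.

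One of the 9 sets of probes that varied together passed the threshold between groups in the unpaired test. Set D held 39 probes, formed without regard to group, of which 22 were among the probes that rose and 0 among those that fell. Its mean lay -1.06 ± 0.76 log2 units (SD, n = 8) from the probes' medians in controls and 0.93 ± 0.73 (SD, n = 8) in exposed samples, a difference of 1.99 or 3.98-fold (two-sided exact permutation p = 0.000311, adjusted p = 0.00280 over 9 sets). The difference was 2.14 on slide 1 and 1.84 on slide 2, with an exact permutation p of 0.0286 on each, and lay between 1.76 and 2.18 when 1 array at a time was left out. Cyfluthrin 7, at -0.37, was the lowest exposed array, and control 4, at -0.27, the highest control. None of the other 8 sets passed the threshold between groups after adjustment in the unpaired test (lowest adjusted p = 0.369, for set C, from exact permutation tests). With same-numbered arrays taken as pairs, set B passed it too: it was higher in the exposed array of all 8 pairs, by 0.25 to 2.20 log2 units and 0.88 ± 0.73 (SD, n = 8) on average (exact sign-change p = 0.00781, the lowest that 8 pairs allow, adjusted p = 0.0352 over 9 sets; unpaired exact permutation p = 0.290, adjusted p = 0.532), as did set D (adjusted p = 0.0352) and none of the other 7 (lowest adjusted p = 0.316). Of the 634 probes in the 9 sets, 23 were among the 360 changed probes.

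Chance division of the arrays is argued against, but not excluded, as the origin of the count of changed probes. Of 100 splits of the 16 arrays into 8 and 8, only 1, the real one, gave as many, with 360 probes against 1 for the highest of the others. These 100 are a sample of the possible splits. Splits balanced over slides were not tested apart, although 240 probes differed between slides.

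There were 30 pairs of changed probes with adjacent places in the order of tested probe numbers, where random placement within each probe group gave 18.0 on average and as many in a share of 0.0043 of the placements. Without the densest stretch of low p, picked after seeing it, there were 24 pairs against 16.8, and the share was 0.0484; both shares treat probes as independent, which the correlation of neighbours given below goes against, so chance stays open. Neighbouring numbers did not lie close together on the glass: the median distance of such pairs was 0.873 of that of random pairs (95% bootstrap interval 0.724 to 1.38), where a local fault of the array was to give under 0.5, which argues against one. A candidate explanation is that neighbouring numbers hold transcripts that vary together for reasons other than exposure: among unchanged probes, the deviations of 6552 adjacent pairs from their group means had a mean correlation of 0.080, against 0.035 for random pairs. The excess of 0.0446 ± 0.0054 (SE, with pairs taken as independent, which they are not) fell between the 0.05 set for this explanation and the 0.02 set against it, so it stays open.

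Some dim probes that were not tested lay far above background in a few samples. In 148 of the 1262 untested probes, at least 1 array was well above background and over 3 log2 units above the probe's median (93 on 1 array, 55 on 2 or more). Of these, 66 were high in control 1, 63 in cyfluthrin 2, 23 in control 4 and 22 in cyfluthrin 1, and no more than 17 in any of the remaining arrays.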
